A study of Drosophila melanogaster with 20 samples.

How the data were processed

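Polyadenylated RNA from pooled heads of adult male Drosophila melanogaster, taken from mixed-sex populations, had been sequenced as single-end reads. The 20 libraries fall into 4 groups by age and genotype: young wild type (7 days, n = 5), midlife wild type (22 to 23 days, n = 4), young chm/+ (7 days, n = 6) and midlife chm/+ (22 to 23 days, n = 5). The processing notes name TopHat2 2.0.5, the genome build BDGP5 and edgeR without a version. The read counter, the annotation and the low-count filter are not given in the sources used here. The deposited table holds 9831 genes, and its values, treated here as signal, are normalized counts that the authors adjusted to a common library size. The values are not whole numbers, and whole reads could not be recovered from them: with a tolerance of 0.02, between 1.95% and 14.7% of the low values tested per library lay on whole multiples of a fitted step. In 3 libraries no step could be fitted. A count model was therefore not run, and read depth is unknown, so no counting intervals or detection floors are given. Column totals ran from 27572012 to 30470376 normalized counts per library. For 226 genes the table gave no symbol, and 3 of these were named from the reference annotation. That annotation is of a later build than BDGP5, so no coordinates are given and chromosome arms are those of the table.

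Columns carry a group in their names but no replicate number that ties them to single listed samples, so libraries are named here by their column names, such as 2uy1 (young wild type), 2uo1 (midlife wild type), CHMy1 (young chm/+) and CHMo11 (midlife chm/+). Values were taken as log2(value + 14.48), the addend being 0.5 CPM at the mean column total. Genes were kept with at least 1 CPM in at least 4 libraries, which removed no gene. One linear model with a mean per group was fitted to all 20 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean trend. The 5 comparisons drawn from it were midlife minus young in each genotype, the difference between these 2 changes, and chm/+ minus wild type at each age. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over the 9831 genes tested, within each comparison. Adjusted p values for genes are from limma throughout. Replicates were treated as independent, which the sources do not state. Replicate libraries of a group correlated across genes at r = 0.972 to 0.997, where genes are not independent replicates.

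Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists in each comparison. Of 26 lists of pathways, complexes, cell types and possible carry-over tissues, 23 had at least 3 measured members and were tested, which makes 115 tests. List members rest on symbols, so the prefix that defines the cuticle list also took in Cpr, a P450 reductase, and the mitochondrially encoded list holds ribosomal and transfer RNAs. The lysine acetyltransferase list also holds the adaptor gene Ada2b and an N-terminal acetyltransferase gene (Nat1 or vnc). Genes named are drawn from chm, the 8 highest and the 8 lowest log2 changes among called genes of each comparison, and the 3 called members with the smallest p of each list with a called member. Not every gene this rule takes is named, so a list without named genes may still hold called ones. A gene outside this rule is said to be so. Overlaps were tested with two-sided Fisher exact tests over the genes tested. These tests, and those on chromosomes, take genes as independent, which they are not. Their p values do not measure the spread between libraries. To compare the size of the change with age, genes were selected in wild type in one set of libraries at an unadjusted p under 0.01, and the median change in the direction of selection was read in the other set, with the sets then swapped and averaged. All relabellings of genotype within age and set were run, with the selected genes held fixed, which gives 12000 permutations. Libraries of each set select genes for one estimate and are relabelled in the other, so the joint permutation p is approximate.

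The first 10 and the last 10 columns each hold all 4 groups and are called column sets. No batch is labelled. A set term was to enter the model only if the first or second principal component, with groups centred, separated the sets without overlap. The rule was worded on listed samples and was applied to table columns. The first component, with 47.0% of the within-group variance, placed library 2uo2 of the second set at 11.9 among the first set, whose lowest score was 4.66, and the next highest of the second set was at -0.96. The sets overlapped, so the set term was run as an alternative. Comparisons, lists, the naming rule, the tests and most alternative settings were chosen before the data were examined. Those settings were 2 other scalings, 2 other addends, other low-value filters, no trend, array weights, the set term, the compared groups alone, each library left out and an estimated list correlation. Single column sets and the omission of libraries CHMo12, CHMo5, CHMy2 and 2uo2, and a block on the number in the column name, were added after the data were seen.

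The procedure was tested on simulated data with 9831 genes, 200 of them changed. For ageing in wild type it called 59% of genes at a true log2 change of 0.5 and 89% at 1, with 8 false calls among 156. For the difference between genotypes it called 85% at 1 and 95% at 2, with 6 false calls among 186. A true size ratio of 0.7 was recovered as 0.694 over 5 draws, and as 0.693 with selection in chm/+. Every changed gene in those draws had that same ratio, so the choice of genes could not bias it. How selection acts when the ratio differs between genes was not simulated. The simulated noise was drawn independently for each gene and library, with no column sets. These rates of true and false calls therefore do not cover structure shared among the real libraries.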

Results

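Gene expression was compared in male heads of 4 groups of libraries, young wild type (n = 5), midlife wild type (n = 4), young chm/+ (n = 6) and midlife chm/+ (n = 5). chm/+ flies carry a mutant copy of chameau (chm), which encodes a histone acetyltransferase of the MYST family. Young flies were 7 days old and midlife flies 22 to 23 days old. Each of 9831 genes was given in normalized counts, with totals of 27572012 to 30470376 per library. Read depth is unknown, so the precision of the values rests on the spread between libraries alone. Of 18 accessory gland and testis gene symbols sought as signs of other body parts, 0 were in the table, and of the gut enzymes sought only the maltase genes Mal-A1 and Mal-A6 were. Every gene in the table had at least 1 CPM in at least 4 libraries, so carry-over into fewer libraries could be missing from it. The yolk protein gene Yp1 stood at 2716 in the young chm/+ library CHMy2 and between 90.8 and 945 in the other 19 libraries.

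The first question was whether chm itself differed with genotype. chm (FBgn0028387, arm 2L) stood at 615 ± 36.6 (SD, n = 5) in young wild type and 321 ± 24.6 (SD, n = 6) in young chm/+, a log2 change of -0.91 (SE 0.07, adjusted p = 9.96e-08). At midlife it stood at 613 ± 46.3 (SD, n = 4) in wild type and 336 ± 22.0 (SD, n = 5) in chm/+, a log2 change of -0.84 (SE 0.07, adjusted p = 8.05e-07). All 11 chm/+ libraries lay below all 9 wild-type libraries, at most 364 against at least 571. chm was not called with age in wild type (log2 change -0.01, adjusted p = 0.972) or in chm/+ (0.07, adjusted p = 0.603).

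**Figure D1:**
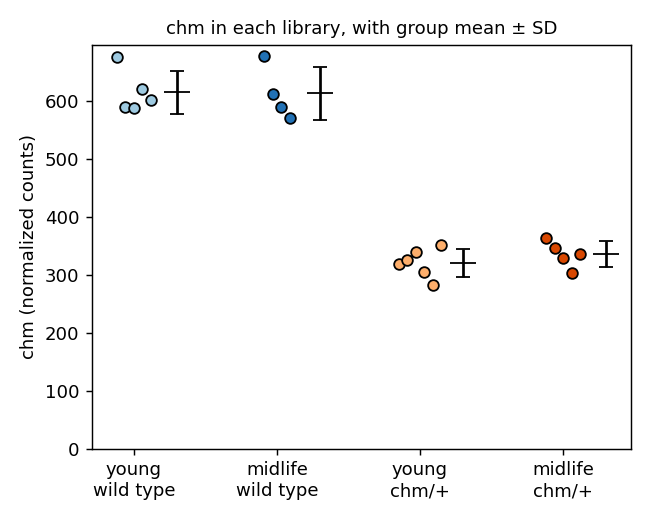
Normalized counts of chm in each of the 20 libraries (points) by group, with mean and SD beside them. The chm/+ libraries lie between 283 and 364 and the wild-type libraries between 571 and 678.

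The second question was which transcripts changed between youth and midlife in wild-type heads. Immune genes rose as a group: of 32 antimicrobial and immune-induced genes, 25 rose, 0 fell and 7 were not called, with a median log2 change of 1.93 (30 rose when adjusted over the list alone; camera adjusted p = 9.60e-14, and adjusted p = 0.399 with an estimated correlation). Library 2uy3 was the highest young wild-type library for 27 of the 32, such as AttA (9439 against 329 to 2228 in the others) and DptB (3199 against 24.2 to 419), and without it 29 rose, with a median of 2.23. PGRP-SC2, an amidase that degrades peptidoglycan, rose from 200.1 ± 184 (SD, n = 5) to 2641 ± 1166 (SD, n = 4), a log2 change of 3.81 (SE 0.56, adjusted p = 6.17e-05). PGRP-SA, a recognition protein of the Toll pathway, rose by 1.98 (SE 0.29, adjusted p = 6.68e-05), and TotM, a stress-induced secreted peptide, rose by 5.35 (SE 0.84, adjusted p = 0.000123). CG6639 had the highest change, from 70.5 ± 104 (SD, n = 5) to 18980 ± 4458 (SD, n = 4), a log2 change of 8.38 (SE 0.68, adjusted p = 6.51e-08), with library 2uy3 at 255.3 and the other young libraries at 15.5 to 41.0. Other steep rises were those of CG43175 (6.35), CG9673 (5.82), CG7763 (5.403), CG10814 (5.33), CG18563 (5.25) and NimC4 (5.01), a receptor of the Nimrod family. Nplp3, a neuropeptide-like precursor, fell from 6724 ± 1236 (SD, n = 5) to 740.2 ± 84.7 (SD, n = 4), a log2 change of -3.15 (SE 0.20, adjusted p = 3.60e-09). The larval serum protein gene Lsp1beta (-2.74), the replication gene Cdc6 (-2.49), the lens gene retinin (-2.16) and the lens crystallin gene Cry (-1.89), which is not the cryptochrome gene cry, fell too, as did CG17005 (-2.58), CG11349 (-2.56) and CG11458 (-2.23). The odorant-binding protein gene Obp56a rose by 2.83 (SE 0.14, adjusted p = 1.23e-10). In all, 2329 of 9831 genes were called, 1218 up and 1111 down, and 292 rose and 52 fell at least 2-fold. The count was 3758 with array weights, 3167 in the first column set alone and 408 in the second, and log2 changes correlated across genes between sets at r = 0.758, where genes are not independent replicates.

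Other lists also shifted with age in wild type. Proteasome genes rose in 16 of 35 and fell in 2 (26 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 6.94e-06, and adjusted p = 0.558 with an estimated correlation). Rpn6, a regulatory subunit, rose by 0.43 (SE 0.09), whereas Rpt3R (-0.85) and Rpt4R (-0.87), paralogues of base ATPase genes, fell. Synaptic and neuronal genes fell in 8 of 24 and rose in 0 (11 fell adjusted over the list alone), with a median of -0.43 (camera adjusted p = 2.57e-05, and adjusted p = 0.558 with an estimated correlation). Among them were Gad1, which makes GABA (-0.80, SE 0.10), ple, the tyrosine hydroxylase gene (-0.60, SE 0.11), and Cha, which makes acetylcholine (-0.48, SE 0.07). Cuticle genes fell in 11 of 28 and rose in 2 (11 and 2 adjusted over the list alone), with log2 changes of -1.21 for Cpr49Ae, -1.51 for Cpr49Ag and -1.04 for Cpr47Ee (median -0.27, camera adjusted p = 0.00145, and adjusted p = 0.399 with an estimated correlation). Detoxification genes rose in 8 of 27 and fell in 0 (8 adjusted over the list alone), GstE9 by 0.88 and Cyp4e2 by 0.84 (median 0.30, camera adjusted p = 0.00175, and adjusted p = 0.399 with an estimated correlation). Haemocyte genes rose in 3 of 8 (7 adjusted over the list alone), the phagocytosis receptor gene NimC1 by 1.85 (SE 0.32) and Hml by 1.26 (SE 0.26), with a median of 0.53 (camera adjusted p = 0.00587, and adjusted p = 0.399 with an estimated correlation). The insulin-like peptide genes Ilp5 (from 964 ± 185 to 467 ± 52.9, SD, n = 5 and n = 4) and Ilp3 (log2 change -1.45, SE 0.27) fell, and Thor, a translation repressor, rose by 0.73 (SE 0.14), while the insulin list as such had 3 rising and 2 falling of 17 (4 and 2 adjusted over the list alone) and was not called (camera adjusted p = 0.234). Odorant-binding protein genes rose in 8 of 25 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0610), and head fat body genes rose in 5 of 13 and fell in 2 (5 and 3 adjusted over the list alone; camera adjusted p = 0.473).

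Weaker list shifts in wild type depended on single libraries. Phototransduction genes fell in 9 of 29 (10 fell and 2 rose adjusted over the list alone), among them the exchanger gene Calx (-0.76, SE 0.09) and eys (-0.65, SE 0.11), with a median of -0.17 (camera adjusted p = 0.0228, and adjusted p = 0.560 with an estimated correlation), and adjusted p = 0.0728 without 2uo4. Oxidative phosphorylation genes fell in 3 of 32 (1 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0273, and adjusted p = 0.757 with an estimated correlation). That call was lost without 2uy2, 2uy3 or 2uo1, with adjusted p up to 0.383. Among them sesB, a mitochondrial ADP/ATP carrier gene, fell by 0.51 on the log2 scale (SE 0.12). Lipid genes rose in 3 of 17 (5 adjusted over the list alone), among them bmm, a triglyceride lipase gene (0.97, SE 0.16), with a median of 0.15 (camera adjusted p = 0.0451, and adjusted p = 0.558 with an estimated correlation), lost without 2uy1, 2uy3, 2uo1, 2uo2 or CHMo12, with adjusted p up to 0.130.

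The next question was how chm/+ heads changed over the same interval. Immune genes rose here too, 29 of 32 with 0 fallen (29 adjusted over the list alone) and a median log2 change of 2.13 (camera adjusted p = 2.50e-21, and adjusted p = 0.158 with an estimated correlation). The antimicrobial peptide gene Drs rose from 695 ± 139 (SD, n = 6) to 21186 ± 12459 (SD, n = 5), a log2 change of 4.71 (SE 0.68, adjusted p = 8.22e-05). AttA (4.61), AttC (4.55), DptB (4.53), Dro (4.43) and AttB (4.42), also antimicrobial peptide genes, rose likewise, as did CG6639 (7.29) and CG18563 (4.63). PPO1, a prophenoloxidase gene of crystal cells, fell from 1285 ± 1085 (SD, n = 6) to 87.8 ± 41.8 (SD, n = 5), a log2 change of -3.37 (SE 0.46, adjusted p = 4.03e-05). Nplp3 (-2.66), Cdc6 (-2.50), retinin (-2.27), Lsp1beta (-2.11) and Cry (-1.93) fell, as did CG11458 (-2.66) and CG11349 (-2.29). Cuticle genes fell in 18 of 28 and rose in 3 (18 and 4 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 3.16e-07, and adjusted p = 0.153 with an estimated correlation), such as Cpr49Ag (-1.43) and Cpr49Ae (-1.08). Oxidative phosphorylation genes fell in 12 of 32 and rose in 0 (16 fell adjusted over the list alone), with a median of -0.28 (camera adjusted p = 3.16e-07, and adjusted p = 0.517 with an estimated correlation), such as Cyt-c-p, the cytochrome c gene (-0.41, SE 0.07), and CoVb (-0.31, SE 0.08). Ilp3 (-1.65) and Ilp5 (-0.93) fell, InR, the insulin receptor gene, rose by 0.82 (SE 0.14) and Obp56a rose by 2.49 (SE 0.12). In all, 1572 genes were called, 848 up and 724 down, with 168 up and 53 down at least 2-fold. The count was 1905 in the first column set alone and 365 in the second, and in chm/+ libraries alone 851 with the column number as a replicate block and 1277 without, and log2 changes correlated across genes between sets at r = 0.801.

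Weaker list shifts in chm/+ again depended on single libraries. Synaptic genes fell in 3 of 24 (3 adjusted over the list alone), with Gad1 at -0.59 (SE 0.09), a median of -0.20 (camera adjusted p = 0.0132, and adjusted p = 0.901 with an estimated correlation), lost without CHMo11 or CHMy12, with adjusted p up to 0.0611. Acetyl-CoA and TCA cycle genes fell in 3 of 22 (5 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0217, and adjusted p = 0.712 with an estimated correlation), and adjusted p = 0.0716 without CHMy2. Detoxification genes rose in 6 of 27 and fell in 1 (6 and 1 adjusted over the list alone), with GstD2, a glutathione transferase gene, at 1.42 (SE 0.28) and a median of 0.18 (camera adjusted p = 0.0321, and adjusted p = 0.517 with an estimated correlation), lost without CHMy3, CHMy4 or CHMo11, with adjusted p up to 0.0574. Phototransduction genes fell in 6 of 29 and rose in 2 (7 and 5 adjusted over the list alone), with Calx at -0.50 (SE 0.08) and a median of -0.12 (camera adjusted p = 0.0380, and adjusted p = 0.818 with an estimated correlation), lost without CHMo3, CHMo11, CHMo5, CHMy11 or CHMy12, with adjusted p up to 0.161.

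**Figure D2:**
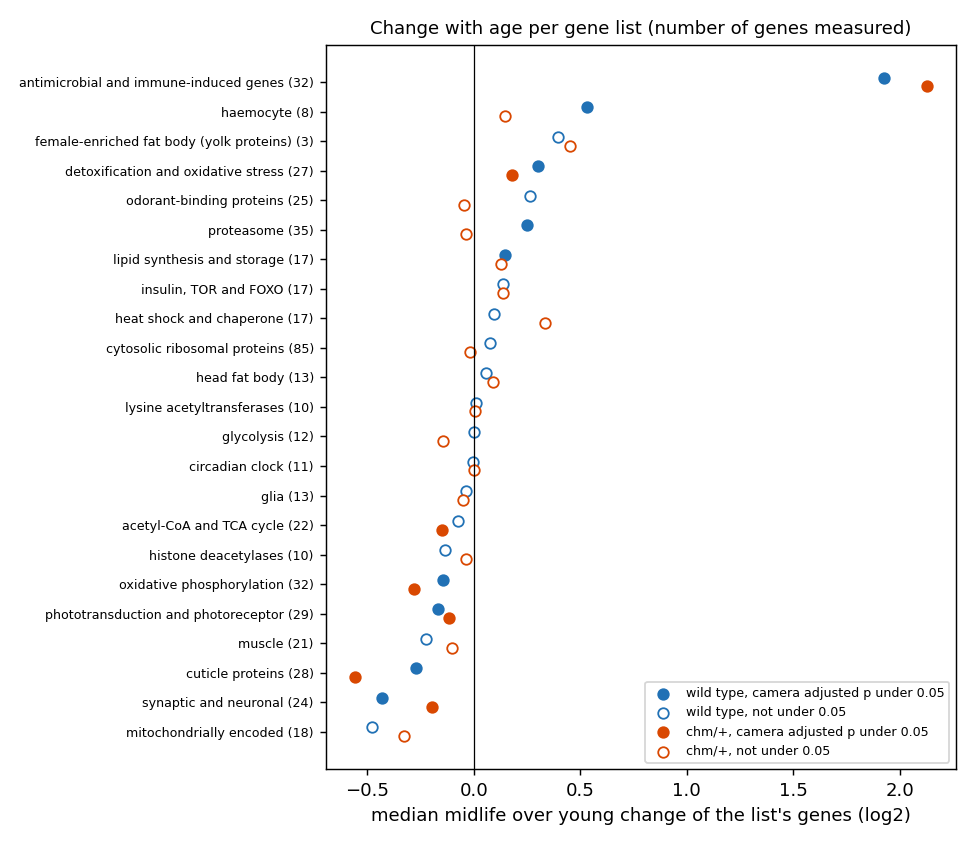
Median log2 change with age of each tested gene list (number of genes measured beside its name) in wild type and chm/+, filled where camera with the preset correlation gave an adjusted p under 0.05. The immune list lies at 1.93 in wild type and 2.13 in chm/+.

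The changes with age overlapped between genotypes. Of 1218 genes that rose in wild type, 650 also rose in chm/+, against 105 expected (odds ratio 48.6, Fisher's exact test), and 96.2% had the same sign. Of 1111 that fell, 494 also fell in chm/+, against 81.8 expected (odds ratio 29.5), and 97.9% had the same sign. None, 0 genes, was called in opposite directions. Log2 changes correlated across genes at r = 0.827 (Spearman 0.739), and the 2 comparisons share no library. Overlap over both directions was 1144 genes, and 173 in the second column set alone.

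Genes selected in wild type changed less in chm/+ when selection and estimate used different libraries. The median change in the direction of selection was 0.60 in wild type and 0.43 in chm/+, a ratio of 0.716 (two-sided permutation p = 0.0153). Genes selected in chm/+ gave 0.50 and 0.49, a ratio of 0.975 (permutation p = 0.810). Selection over both genotypes, added after the data were seen, gave a ratio of 0.797 (permutation p = 0.176).

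The difference between the 2 changes with age was then tested gene by gene. It was called for 35 genes, 33 more negative and 2 more positive in chm/+. Of the 33, 32 rose in wild type, with a median log2 change of 1.93. In chm/+ 20 of them rose, 12 were not called and 1 (CG5535, outside the naming rule and chosen after its values were seen) fell, with a median of 0.47. CG10814 rose from 5.89 to 781 in wild type and from 4.94 to 53.2 in chm/+, a difference in log2 change of -3.64 (SE 0.40, adjusted p = 6.23e-05). CG43175 rose from 3.68 to 1670.2 and from 5.43 to 99.3 (-4.26, SE 0.67, adjusted p = 0.00699), and NimC4 from 9.08 to 746 and from 14.1 to 105 (-3.23, SE 0.55, adjusted p = 0.00934). CG14153 rose from 186 to 1319 in wild type and stood at 287 and 317 in chm/+ (-2.61, SE 0.27, adjusted p = 6.23e-05). Jhe, the juvenile hormone esterase gene, differed by -2.94 (SE 0.55, adjusted p = 0.0169), a call lost without 2uo4 (adjusted p = 0.0589). SMC2, a condensin gene, stood at 217 and 296 in wild type and rose from 534 to 1869 in chm/+ (1.39, SE 0.23, adjusted p = 0.00826). CG7763 (-2.95), spheroide (-2.73) and CG6891 (-2.40) also differed, with calls that single libraries ended, the highest adjusted p being 0.144, 0.0952 and 0.0952, each without 2uo4. For CG7763 these were all libraries but CHMo3, CHMy2, CHMo12 and CHMo5. For spheroide they were 2uo4, 2uo5, 2uy3, CHMo2, CHMy4, 2uo2, 2uy4, 2uy5, CHMo11 and CHMy12, and for CG6891 2uo4, 2uo5, CHMo2, CHMy3, CHMy4, 2uy4 and 2uy5. CG17005 fell less in chm/+ (1.08, SE 0.21, adjusted p = 0.0204), a call lost without 2uo5 or 2uo1 (adjusted p = 0.0575 and 0.0567). In library CHMo12 the 33 genes lay near the young chm/+ level, and their position there was 0.079 on a scale from young (0) to other midlife chm/+ libraries (1). The count was 19 without 2uo4, 22 without CHMo2, 66 without CHMo5, 100 with array weights, 69 in the first column set alone and 1 in the second. It was reached or exceeded in 5 of 100 splits of the libraries, and log2 differences correlated across genes between sets at r = 0.475.

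No list had a member called for the difference over all 9831 genes, where limma gave 655 genes at an unadjusted p under 0.05. Proteasome genes had a median of -0.28 with 2 of 35 positive (0 called adjusted over the list alone; camera adjusted p = 1.26e-14, and adjusted p = 0.327 with an estimated correlation). Haemocyte genes had a median of -0.76 with 0 of 8 positive (3 called lower adjusted over the list alone; camera adjusted p = 1.05e-05, and adjusted p = 0.188 with an estimated correlation). Heat shock and chaperone genes had a median of 0.35 with 17 of 17 positive (0 called adjusted over the list alone; camera adjusted p = 0.000622, and adjusted p = 0.485 with an estimated correlation). Odorant-binding protein genes had a median of -0.29 (0 called adjusted over the list alone; camera adjusted p = 0.00119, and adjusted p = 0.327 with an estimated correlation). Synaptic genes had a median of 0.22 with 24 of 24 positive (0 called adjusted over the list alone; camera adjusted p = 0.000794, and adjusted p = 0.712 with an estimated correlation), lost without 2uo2 (adjusted p = 0.0605). The direction of the synaptic test turned with CHMo12, CHMy2 and 2uo2 left out together (camera adjusted p = 0.775). Oxidative phosphorylation genes had a median of -0.13 (0 called adjusted over the list alone; camera adjusted p = 0.00841, and adjusted p = 0.715 with an estimated correlation), lost without CHMy2, CHMy3, 2uo2, 2uy4, 2uy5 or CHMo5, with adjusted p up to 0.140.

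**Figure D3:**
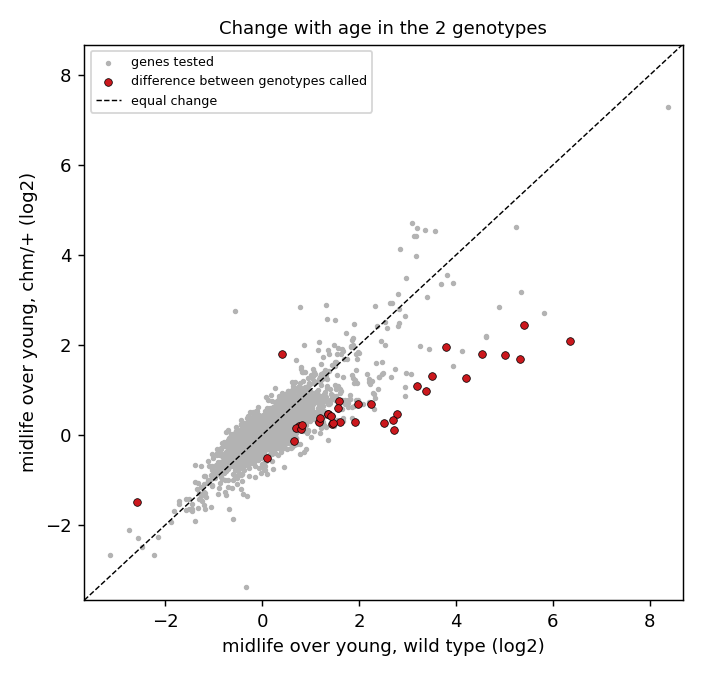
Log2 change from young to midlife in wild type (horizontal) and chm/+ (vertical) for each of 9831 genes, with the 35 genes called for the difference in red and a dashed line of equal change. Changes correlate at r = 0.827 across genes.

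**Figure D4:**
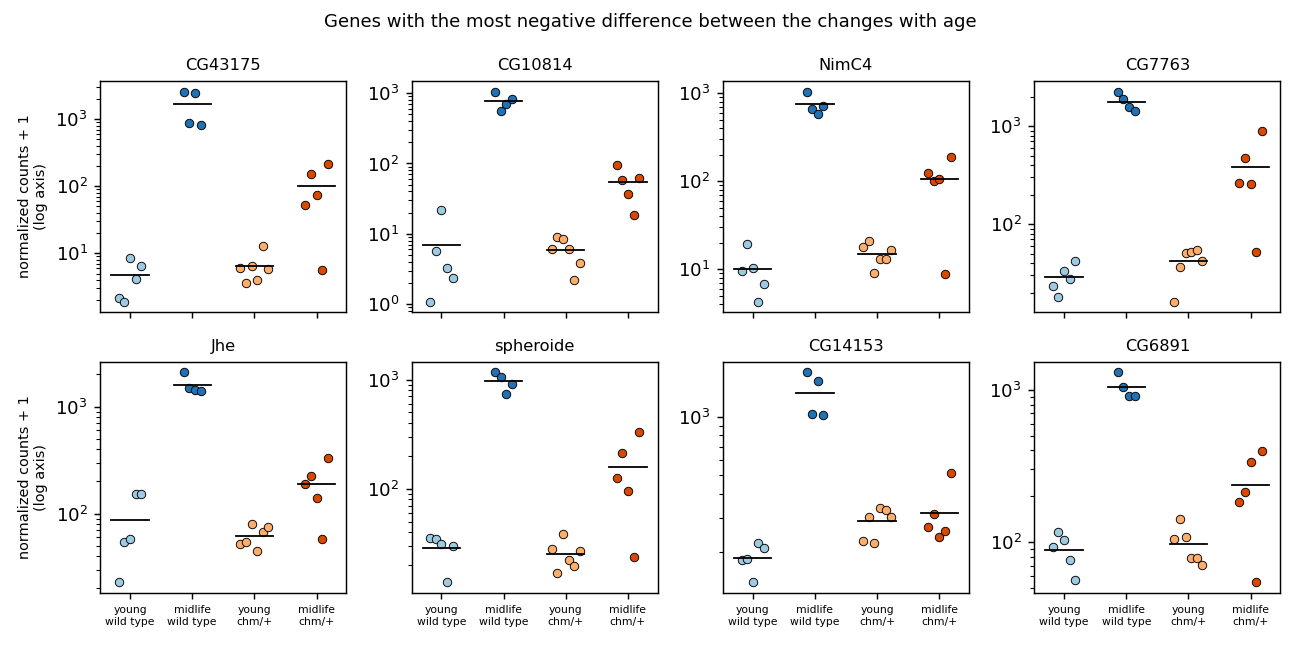
Normalized counts plus 1 (log axis) in each library for the 8 genes with the most negative difference, points by group with a line at the mean. CG10814 has a mean of 781 in midlife wild type and 53.2 in midlife chm/+.

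Genotypes were next compared within young heads. Cyp6a2, a detoxification P450 gene, stood at 1979 ± 501 (SD, n = 5) in wild type and 360.3 ± 176 (SD, n = 6) in chm/+, a log2 change of -2.54 (SE 0.28, adjusted p = 1.56e-05). Cyp6a14 (-2.01), the photolyase gene phr (-1.76), the serotonin receptor gene 5-HT1B (-1.27), the ionotropic receptor gene Ir54a (-1.19), CG7271 (-1.15) and CG4962 (-1.15) were also lower. CG16836 was higher by 2.09 (SE 0.26), CG32444 by 1.83 (SE 0.16) and the noncoding gene pncr009:3L by 1.80 (SE 0.11, adjusted p = 6.90e-09). Tsp42Er (1.74), CG18673 (1.70), Ugt37b1 (1.54), the cell cycle gene Cks30A (1.502) and CG32984 (1.41) were higher too, and SMC2, outside the naming rule here and chosen after its values were seen, was higher by 1.20. In all, 143 genes were called, 88 higher and 55 lower. The odorant-binding protein list had 3 of 25 higher (4 adjusted over the list alone), such as Obp56a (0.70, SE 0.12), with a median of 0.21 (camera adjusted p = 0.00137, and adjusted p = 0.325 with an estimated correlation). Detoxification genes had 1 higher, GstE1 (0.38, SE 0.06), and 1 lower, Cyp6a2 (8 and 1 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00137, and adjusted p = 0.325 with an estimated correlation). CG9505 (-1.17, adjusted p = 0.0414) was lost on leaving out any 1 library other than CHMo2, CHMy2, CHMy4, CHMo11, CHMo12 or CHMo5, with adjusted p up to 0.141. The count was 91 without 2uy1, 3194 with array weights, 394 with the set term, 290 in the first set alone and 17 in the second, and log2 changes correlated across genes between sets at r = 0.569.

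Genotypes were last compared at midlife. SMC2 stood at 296 ± 33.4 (SD, n = 4) in wild type and 1869 ± 312 (SD, n = 5) in chm/+, a log2 change of 2.59 (SE 0.17, adjusted p = 2.66e-08). CG16836 (1.84), CG5999 (1.82), Cks30A (1.74), pncr009:3L (1.65), CG11349 (1.48), CG32984 (1.37) and CG32444 (1.32) were higher. CG43175 (-4.12), CG10814 (-3.63), Jhe (-3.16), CG9673 (-3.11), NimC4 (-2.93), spheroide (-2.85), CG30160 (-2.60) and Tsp42Eb (-2.60) were lower, the last pair with near-identical values in every group. Cyp6a2 (-1.83, SE 0.31) and the cuticle gene Cpr62Bb (-0.72, SE 0.09) were lower, and the flight muscle gene fln (0.90, SE 0.17) was higher. In all, 192 genes were called, 70 higher and 122 lower. Of genes higher in young chm/+, 30 were also higher at midlife, against 0.63 expected (Fisher's exact p = 6.05e-45), and of those lower, 23 were also lower, against 0.68 expected (Fisher's exact p = 2.20e-30). Both tests take genes as independent, which they are not. Proteasome genes had a median of -0.15 with 1 of 35 positive (0 called, also adjusted over the list alone; camera adjusted p = 1.29e-05, and adjusted p = 0.913 with an estimated correlation). Synaptic genes had a median of 0.26 (0 called, also adjusted over the list alone; camera adjusted p = 0.000110, and adjusted p = 0.913 with an estimated correlation). The count was 121 without 2uo4, 626 with array weights, 357 with the set term, 119 in a model of the compared groups alone, 285 in the first set alone and 17 in the second, and log2 changes correlated across genes between sets at r = 0.671.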

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

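The splits of the libraries for the 5 comparisons were planned, and the other tests of explanations in this part were chosen after the results were seen. The haemocyte test took its form after earlier forms, one on the 33 genes at midlife, which was void, and one on the difference, which left it open, had been run, and its bound was moved from the lowest marker, which would have argued against the explanation, to every marker. The column set test replaced earlier forms, on the SE over genes and on the set term, both of which argued against the explanation.

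In 576 groups of 4 to 6 libraries tested for a library far from the rest, 39 had one, where chance gives about 1 in 20. Libraries CHMo12 and CHMy2 had 6 each. In midlife chm/+, CHMo12 was low for NimC4 (7.86 against 101 to 189 in the others), CG30160 and Tsp42Eb (38.7 each against 294 to 594) and Obp83cd (35.2), and high for Cpr49Ae (1076) and 5-HT1B (429.7). In young chm/+, CHMy2 was low for CG7763 (15.2), ple (1322), Cks30A (165) and CG30160 (24.7), and high for the yolk protein list (mean log2 deviation 2.18) and the proteasome list (0.23). Other libraries of young chm/+ stood apart for TotM (703 in CHMy4), AttC (2576 in CHMy4), CG43175 (11.7 in CHMy11) and bmm (6707 in CHMy1). Others of midlife chm/+ did so for CG11349 (117 in CHMo11), Hsp83 (31070 in CHMo11), Rpt4R (106 in CHMo11), ple (849.5 in CHMo3), Hsp67Ba (295 in CHMo5) and Cyp6a14 (281 in CHMo5). In young wild type these were CG6639 (255.3), PGRP-SC2 (528.5) and Drs (4939) in 2uy3, Ilp5 (646), InR (1005) and the insulin list (-0.24) in 2uy1, and CG9673 (9.82), spheroide (13) and Obp83g (17.23) in 2uy4. In midlife wild type they were Mlp84B (2408) and Jhe (2102) in 2uo4, CG11349 (10.2) and Cpr62Bb (528) in 2uo5, Cpr49Ag (361), pncr009:3L (15.9) and Ir54a (142) in 2uo1, and 5-HT1B (459) in 2uo2.

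The change with age differed between genotypes for 35 genes. Those the naming rule takes were CG43175 (-4.26), CG10814 (-3.64), NimC4 (-3.23), CG7763 (-2.95), Jhe (-2.94), spheroide (-2.73), CG14153 (-2.61), CG6891 (-2.40), CG17005 (1.08) and SMC2 (1.39). Tsp42Er (-2.31, adjusted p = 0.0433), outside the rule here and taken by it at young age, lost its call with any of 14 libraries left out, with adjusted p up to 0.144 without 2uo4. Lists that differed in camera with the preset correlation had medians of -0.28 (proteasome), -0.76 (haemocyte), -0.29 (odorant-binding proteins), -0.13 (oxidative phosphorylation), 0.22 (synaptic and neuronal) and 0.35 (heat shock and chaperone), and with an estimated correlation 0 of these were called. The size ratio differed from equality for genes selected in wild type (0.716, permutation p = 0.0153), while selection in chm/+ gave 0.975 (permutation p = 0.810) and selection over both genotypes 0.797 (permutation p = 0.176). Selection on the wild-type change favours genes that change more in wild type, so 0.716 does not measure all genes. Over all genes, covariances between column sets gave an SD of the changes in chm/+ of 0.827 times that in wild type, which was not tested. Of 100 splits of the libraries, 5 called at least 35 genes, so chance is not excluded for this count. The highest other split called 4141, which points to structure among the libraries that the groups do not describe. With the column set as a term the count was 46, 3 of 100 splits within age and set, the real one included, reached it and the highest other gave 60. This form was added after the planned splits had left chance open, so chance is not taken as excluded by it.

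The 33 genes with a more negative change with age in chm/+, 32 of which rose in wild type, were weighed first. Leaving out CHMo12 left 34 genes called lower, 28 of them shared, which argues against that library as the cause. A slower course of all ageing changes at the ratio of 0.716 is argued against by genes selected in chm/+, with a ratio of 0.975. A difference of -0.01 was seen there and -0.14 was needed (SD 0.05). The needed value takes 0.716 as exact, so a milder uniform slowing, such as the ratio of 0.797 from selection over both genotypes, stays open. A shift common to a column set cancels in this comparison (median -1.30 with and without the set term) only with 2uo2 counted in the second set. The first component of 2uo2 (11.9) lay among those of the first set, so such a shift stays open, as does one that differs between groups. The 65 genes called lower in the first set had a median of -0.80 in the second, 62 of them negative. Over 100 relabellings of genotype within age there, the two-sided exact p was 0.08, and only 1, the real labelling, had a median at least as low. Fewer haemocytes in midlife chm/+ heads stay open: 7 of 8 marker genes were lower at midlife (NimC1 -0.68, Hml -0.44, eater -0.18) with 0 called, and 62 of the genes called lower in the first set, the markers left out, had a midlife median of -0.60 (SE 0.17 over genes, which are not independent) in the second, below the lowest marker, Pxn (-0.36, SE 0.15), by slightly more than the combined SE of 0.23, but not below NimC1 (-0.31, SE 0.43) or Cg25C (-0.32, SE 0.35) by more than the combined SE of each. An effect of the genotype on these genes stays open too, and neither genetic background nor a change within haemocytes was tested.

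Library CHMo12 lay near the young chm/+ level for the same genes, at 0.079 where the other 4 midlife chm/+ libraries are set to 1. The 1877 other genes taken were called with age in wild type and had no difference between genotypes at an unadjusted limma p under 0.05. Over these CHMo12 lay at 0.605, lower than the other 4 (0.897 to 1.07) there too. That choice of genes used CHMo12 itself and can raise its position, so 0.605 alone does not decide on a young library with a wrong label. Over all genes, without groups centred, its first principal component was -4.65. This lay outside the range of young chm/+ (11.7 to 21.3) and short of the other midlife chm/+ libraries (-26.5 to -17.5). The second column set as the cause is argued against by CHMo5 of that set, at 1.34 on the 33 genes. A library from flies of mixed ages was not tested, and no biological explanation for one library was tested.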

How the results depend on the processing

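Single column sets, the joint omissions, the set term with an estimated correlation and selection over both genotypes, and the block, were chosen after seeing the data. Numbers in the column names are not those of the listed samples, and whether they pair libraries is unknown. Deviations of same-numbered libraries correlated at -0.53 to 0.35 over age in wild type, 0.17 to 0.64 over age in chm/+ (4 pairs, each within a column set), -0.52 to 0.66 at young age and 0.13 to 0.41 at midlife, and not every library correlated best with its own number. With the number as a replicate block the 5 counts were 2468, 1564, 39, 153 and 127, and in chm/+ libraries alone the block gave 851 for ageing, where 1277 were called without it and 1925 with the set term. The count models were not run, since whole reads were not recovered, and removing the low-value filter moved nothing, since it removed no gene. The other scalings, addends, stricter filter and no trend kept all 5 counts of called genes within 1.5 times. Array weights gave 3758 genes for ageing in wild type, 100 for the difference, 3194 and 626 for genotype at young age and midlife, and an overlap of 1780. The set term gave 394 and 357 for genotype at young age and midlife, and the compared groups alone gave 119 at midlife. Each column set alone has 2 or 3 libraries per group. The first gave 3167 and 1905 for ageing in wild type and chm/+, 69 for the difference and 290 for genotype at young age. The second gave 408 and 365 for ageing in wild type and chm/+, and 1 for the difference. It gave 17 for genotype at each age and an overlap of 173. The second set holds 2uo2, whose first component (11.9) lay among those of the first set. With each library left out in turn the counts ran from 1607 to 2399 (ageing in wild type), 1237 to 1740 (ageing in chm/+), 19 to 66 (difference, 19 without 2uo4, 22 without CHMo2 and 66 without CHMo5), 91 to 176 (genotype at young age, 91 without 2uy1), 121 to 262 (genotype at midlife, 121 without 2uo4), 924 to 1364 (overlap) and 32 to 43 called lists. The chm log2 change ran from -0.94 to -0.88 at young age and from -0.87 to -0.79 at midlife. With CHMo12 and CHMo5 left out the 5 counts were 2401, 1452, 52, 151 and 179, and with CHMo12, CHMy2 and 2uo2 left out 2198, 1759, 40, 137 and 132. Of 39 list calls, 22 held with each library left out and 13 in every alternative but the block, not run for single calls, and an estimated correlation, with which 0 were called, also with the set term. Of 178 calls of named genes, 149 held with each library left out and 74 in every alternative but the block. The synaptic list's difference turned direction with CHMo12, CHMy2 and 2uo2 left out (adjusted p = 0.775), and the muscle list at young age did so in the second set alone (adjusted p = 0.154). The size ratio was 0.975 with selection in chm/+ and 0.797 with selection over both genotypes. Fewer libraries alone would not give the low counts of the second set, since the first also has 2 or 3 per group. Apart from fewer libraries or genes for the other shifts, no cause was tested. Depth is unknown, so what it limits cannot be stated.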

Other observations

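The splits of the libraries for the 5 comparisons and the test of young chm/+ heads against wild-type ageing were planned before their results were seen, and the tests on the X chromosome were chosen after, the one of power in place of an earlier form on the X share of wild-type ageing calls (13.9%), which had been read as arguing against it.

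Several further gene groups differed between genotypes in camera with the preset correlation. Mitochondrially encoded transcripts had a median log2 change of 0.79 in young chm/+, with 18 of 18 positive and 0 called (0 adjusted over the list alone; camera adjusted p = 0.00132, and adjusted p = 0.659 with an estimated correlation). At midlife the median was 1.00 with 18 of 18 positive (0 called, also adjusted over the list alone; camera adjusted p = 0.000705, and adjusted p = 0.913 with an estimated correlation), lost without 2uo2 (adjusted p = 0.0560). Heat shock and chaperone genes had a median of -0.27 in young chm/+ (0 called, 2 lower adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.389 with an estimated correlation). With age, 9 of 17 rose and 2 fell in chm/+ (9 and 3 adjusted over the list alone; median 0.34, camera adjusted p = 0.138, not called), Hsp68 by 0.44 (SE 0.11), and 0 rose and 4 fell in wild type (0 and 4 adjusted over the list alone), with Hsp67Bc at -1.05 (SE 0.12), a median of 0.10, a mean of 0.01 and a camera test in the negative direction (adjusted p = 0.543). The lysine acetyltransferase list has 10 genes, chm among them, and not all of them encode such enzymes. It had a median of -0.12 at both ages with chm as the 1 called member (1 adjusted over the list alone; camera adjusted p = 0.00137 and 0.0159, and adjusted p = 0.389 and 0.913 with an estimated correlation). Without chm, whose level the genotype sets, 9 members had medians of -0.10 and -0.12 (0 called, also adjusted over the list alone; camera adjusted p = 0.0497 and 0.349, and adjusted p = 0.659 and 0.913 with an estimated correlation). Ribosomal protein genes had a median of -0.17 at midlife (0 called, also adjusted over the list alone; camera adjusted p = 0.00248, and adjusted p = 0.913 with an estimated correlation), lost without 2uo5, 2uo2, CHMo12 or CHMo5, with adjusted p up to 0.0902.

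In young chm/+, proteasome genes had a median of 0.11 with 0 higher and 1 lower, Rpt3R at -0.55, a call lost with any of 9 libraries left out (adjusted p up to 0.147) (the same adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.659 with an estimated correlation), lost without CHMy2 (adjusted p = 0.0736), the library with high yolk protein transcripts. Lipid genes had a median of 0.11 (1 higher, 2 adjusted over the list alone; camera adjusted p = 0.0187, and adjusted p = 0.389 with an estimated correlation), also lost without CHMy2 (adjusted p = 0.116). Camera at the preset correlation also called head fat body genes in young chm/+ (median 0.18, adjusted p = 0.0347, and adjusted p = 0.325 with an estimated correlation) and haemocyte genes (0.21, adjusted p = 0.0449, and adjusted p = 0.491 with an estimated correlation), each with 0 members called, also adjusted over the list alone. It called muscle genes (-0.21, adjusted p = 0.0335, and adjusted p = 0.659 with an estimated correlation), though the 1 member called, also adjusted over the list alone, was fln, which was higher (0.75). The head fat body call was lost without 2uy1, 2uy3, CHMy2, CHMy4 or 2uy4 (adjusted p up to 0.124), the muscle call without 2uy1, 2uy2, 2uy3, CHMy2 or CHMy4 (up to 0.161) and the haemocyte call without 2uy3, CHMy2, CHMy4, 2uo2, 2uy4, 2uy5 or CHMy12 (up to 0.127). At midlife haemocyte genes had a median of -0.43 (0 called, 2 lower adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.913 with an estimated correlation), and oxidative phosphorylation genes -0.13 (0 called, also adjusted over the list alone; camera adjusted p = 0.0163, and adjusted p = 0.913 with an estimated correlation), lost without 2uo5, 2uo2, CHMo12 or CHMo5, with adjusted p up to 0.189. Lists tested and not called with age in wild type had medians of 0.01 (lysine acetyltransferases), -0.13 (histone deacetylases), -0.07 (acetyl-CoA and TCA cycle), 0.06 (head fat body), 0.14 (insulin), 0.10 (heat shock and chaperone), 0.00 (glycolysis and circadian clock), -0.04 (glia), 0.39 (yolk proteins), -0.22 (muscle), 0.08 (ribosomal proteins), -0.48 (mitochondrially encoded) and 0.26 (odorant-binding proteins). Some of these lists held called members in wild type: 2 of 12 glycolysis genes rose and 1 of 11 clock genes fell. Of 13 glia genes 1 rose and 2 fell, and of 21 muscle genes 1 rose and 2 fell. Of 22 acetyl-CoA and TCA cycle genes 1 rose and 2 fell. The 2 dosage compensation RNAs, too few for a test, had 1 fall in wild type and 0 called in chm/+. The median and the test had opposite signs for heat shock genes in wild-type ageing, head fat body and odorant-binding protein genes in chm/+ ageing, glia and cuticle genes in the difference, phototransduction genes at young age, and head fat body and lipid genes at midlife. The mean alone differed in sign from the test for muscle genes in chm/+ ageing and at midlife and for oxidative phosphorylation genes at young age.

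The X chromosome held few of the genes that differed with genotype, and a smaller share of its genes than of autosomal genes was called with age. It holds 1606 of the genes tested (16.3%), but 5 of 143 genes called at young age (two-sided Fisher's exact p = 1.93e-06) and 16 of 192 at midlife (Fisher's exact p = 0.00152), and for ageing 20.1% of X-linked genes were called in wild type (Fisher's exact p = 0.000197) and 11.6% in chm/+ (Fisher's exact p = 6.33e-08), against 26.0% and 17.7% on chromosome 2 and 23.9% and 16.8% on chromosome 3. A segment carried along with the lesion on chromosome 2 is argued against as the whole cause by chromosome 3, where 3.02% of genes were called in either genotype comparison, against 1.31% on the X (Fisher's exact p = 0.000118) and 3.60% on chromosome 2. Less power on the X stays open, since 21 of 282 genes called in either genotype comparison were X-linked, and so were 22 and 20 of the 282 genes of smallest p for ageing in wild type and in chm/+. Autosomal background that may differ between the stocks cannot be told apart from this: of 53 genes called at both ages 0 were X-linked, but of the 53 genes of smallest p for ageing only 5 in wild type and 2 in chm/+ were (Fisher's exact p = 0.0566 and 0.495 against the 0). The normalized counts used here hold no sequence variants with which to test it, and the reads were not examined.

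A hypothesis that young chm/+ heads are already shifted along the wild-type change with age was tested on separate column sets. The covariance over genes was 0.00937, with -0.00557 and 0.0243 for the genotype effect of the first and the second set. The two-sided permutation p was 0.385 over 200 permutations, with the wild-type changes held fixed, which makes it approximate. The smallest possible permutation p was 0.005, so the test left the question open.

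For ageing, 1 of 100 splits of the libraries, the real one, reached 2329 genes in wild type, with 1541 as the highest other, and 1 reached 1572 in chm/+, with 936 as the highest other. This argues against a random split of independent libraries as the source of these counts. For genotype, 2 of 100 splits reached 143 genes at young age, with 1980 as the highest other, which again points to structure among the libraries, and 1 reached 192 at midlife, with 142 as the highest other, so chance was excluded at 0.05 for both. Splitting chm/+ libraries by column set called 2147 genes, more than the 1277 for age in the same libraries, or 1925 with the set as a term. The fit of all 20 libraries called 2203 for ageing in chm/+ with the set term and 1572 without. Splitting wild-type libraries by column set called 0 genes with limma, against 1945 for age. Library 2uo2 was counted in the second set there although its first component (11.9) lay among the first, so that split does not show that wild type lacked such structure.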
